A study of Mus musculus with 5 samples.

How the data were processed

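Total RNA from 5 tissues of C57BL/6 mice aged 2 to 3 months was profiled on 1-colour miRCURY LNA microarrays, in which probes containing locked nucleic acids capture mature microRNAs. The tissues were brown, inguinal and epididymal adipose tissue and the gastrocnemius and soleus muscles. Per the labels, tissue was frozen on dry ice, RNA was extracted with Trizol and a column kit, and microRNA was labelled with a dye read as Cy3. There was 1 array per tissue, and the labels do not say how many animals gave each RNA. Tissues were not treated as replicates of a class, although muscle against fat sets 2 arrays against 3, so no test was run and no p-value was computed. No difference has a replicate check within a tissue.

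Per the file headers, the authors deposited foreground and background-subtracted intensity for each spot, with 4 spots per probe. Their probe value was the median of those spots after background subtraction. Per the file headers, the authors then divided each probe's intensity by the array's median over microRNAs above 50 in all samples, which gives a normalized intensity that is a ratio to that median. The medians so defined were 446 units for brown, 420.5 for inguinal, 396 for epididymal, 408 for gastrocnemius and 468 for soleus. They could not be rebuilt exactly: a median over mouse probes differed from the scale by a relative gap of up to 0.0466. The authors also deposited the ratio of each pair of arrays, lists of probes past a 2.0-fold ratio in either direction, and a table of correlation coefficients. Per the file headers, those lists left out probes under 50 on both arrays. The scanner software and the probes behind the correlation table are not given in the sources used here. The value table of the whole series held the same normalized intensities, with a largest difference of 5.0e-09 over 1973 rows.

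The design fixed before the data were examined called for spots of 1 probe to be averaged; the deposited medians of spots were used instead, as they came. The main setting used the normalized intensities of the 598 probes naming a mouse microRNA, each name having 1 probe. A probe counted as detected at 50 background-subtracted units or more. On these arrays 160 mouse probes were detected in brown, 148 in inguinal, 157 in epididymal, 165 in gastrocnemius and 170 in soleus, with 123 on all 5 arrays and 207 on at least 1. Empty spots reached at most 2.5 units and negative controls at most 6.0. Viral probes, with no infection named, had a 95th percentile of 77.6 units on soleus and 45.4 on brown fat. The floor therefore did not keep out all of their signal. Microarrays give no depth, so the number of arrays limits the precision. The SD of the log2 values of the 4 spots had a median of 0.15 and a 95th percentile of 0.42 over detected probes. Errors quoted beside a ratio are standard errors from those spots and cover spot-to-spot noise only, not animals, extraction or labelling.

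For each pair of arrays the log2 ratio of normalized intensities was taken. A probe under the floor on 1 side was raised to the higher of its own value and the lowest detected value of that array, and the ratio is given as at least that fold; a probe under the floor on both sides has no fold. A microRNA counted as different when it was at least 2-fold higher or lower in every pair of a comparison, and the fold quoted is then the one nearest to 1. Named microRNAs were the 10 highest and 10 lowest by that ratio in each comparison, and members of 17 lists fixed beforehand. The lists were muscle myomiRs, slow-fibre, brown adipocyte, white adipocyte, Hox cluster, Dlk1-Dio3, miR-17-92 with its paralog clusters, let-7, miR-29 and miR-30, leukocyte, red cell, endothelial, smooth muscle and stromal, epithelial, neural and liver microRNAs, and reported repressors of brown adipocyte formation. For each list the median log2 ratio, averaged over the pairs, was placed as a percentile among 10000 random lists of the same size matched on mean level (drawn from 40 neighbours), as a description of these arrays. Names are those of the array design, and the array's unsuffixed miR-193 was not matched to the listed miR-193a. Some lists share members. miR-133a and miR-133b are muscle microRNAs and repressors, miR-182 and miR-203 brown and epithelial, and miR-155 a repressor and leukocyte. miR-93 and miR-106b are repressors and of the miR-17-92 list, and miR-143 is white and stromal. miR-10b and miR-196a are white and Hox, and miR-30b and miR-30c brown and of the miR-29 and miR-30 list. The slow-fibre members, miR-208b and miR-499, are also on the muscle list. Probes of closely related microRNAs can bind each other's targets, so their separate values are uncertain. Such are the let-7s, the miR-30s, miR-133a with miR-133b, miR-1 with miR-206, and miR-196a with miR-196b.

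The calling step was tested on simulated data built from the brown adipose levels and spot noise over 598 microRNAs. Called were 0 of 30 microRNAs changed 1.5-fold, 33 of 33 changed 3.0-fold and 23 of 23 changed 8.0-fold, with 0 of 53 unchanged ones. Apart from the set changes, the simulated arrays differed by spot noise only, so false calls were unlikely from the start. Changed microRNAs were counted only where both levels reached the floor, so bounds and scaling were not tested. Alternatives were other floors, other size rules, all probes, no bounds, normexp background correction with an offset of 50 and quantile normalization, scaling by medians or a 75th percentile, no scaling, and, added after the data were seen, scaling by spike-in controls and leaving out single arrays. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The 1258 probes without a name and 39 viral probes entered no comparison in the main setting. They entered the setting with all probes and helped to set the 75th percentile scalings.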

Results

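MicroRNA was measured in brown, inguinal and epididymal adipose tissue, gastrocnemius muscle and soleus muscle, with 1 array each. Brown fat burns fuel for heat, the inguinal and epididymal depots are white fat under the skin and beside the testis, and soleus holds more slow fibres than gastrocnemius. The study profiled microRNA across adipose tissues and muscles, and the design sets brown fat against white fat, the white depots against each other, the muscles against each other, and muscle against fat. Values are normalized intensities, in multiples of the array's median, and folds compare single arrays with no replicate check. Where a comparison holds several pairs of arrays, the fold given is the smallest of them.

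The muscles and the white depots were each closely alike, and the place of brown fat between them depended on the measure. Over the 123 microRNAs detected on every array, Pearson's r of log2 levels was 0.97 between the muscles and 0.94 between the white depots. Brown fat stood at 0.89 with gastrocnemius, 0.88 with soleus, 0.88 with epididymal fat and 0.85 with inguinal fat. Without the muscle list, over 121 microRNAs, it lay nearest to epididymal fat, at 0.92, with 0.89 for gastrocnemius. The lowest value was 0.73, between inguinal fat and soleus. Spearman's rho ran from 0.735 for that pair to 0.966 for the muscles. These are correlations across microRNAs, which are not independent replicates. In the authors' deposited table the order differed, with 0.921 for the white depots above 0.860 for the muscles, and brown fat at 0.909 with epididymal fat, 0.893 with gastrocnemius, 0.826 with inguinal fat and 0.720 with soleus. The lowest there was again inguinal fat and soleus, at 0.593.

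**Figure D1:**
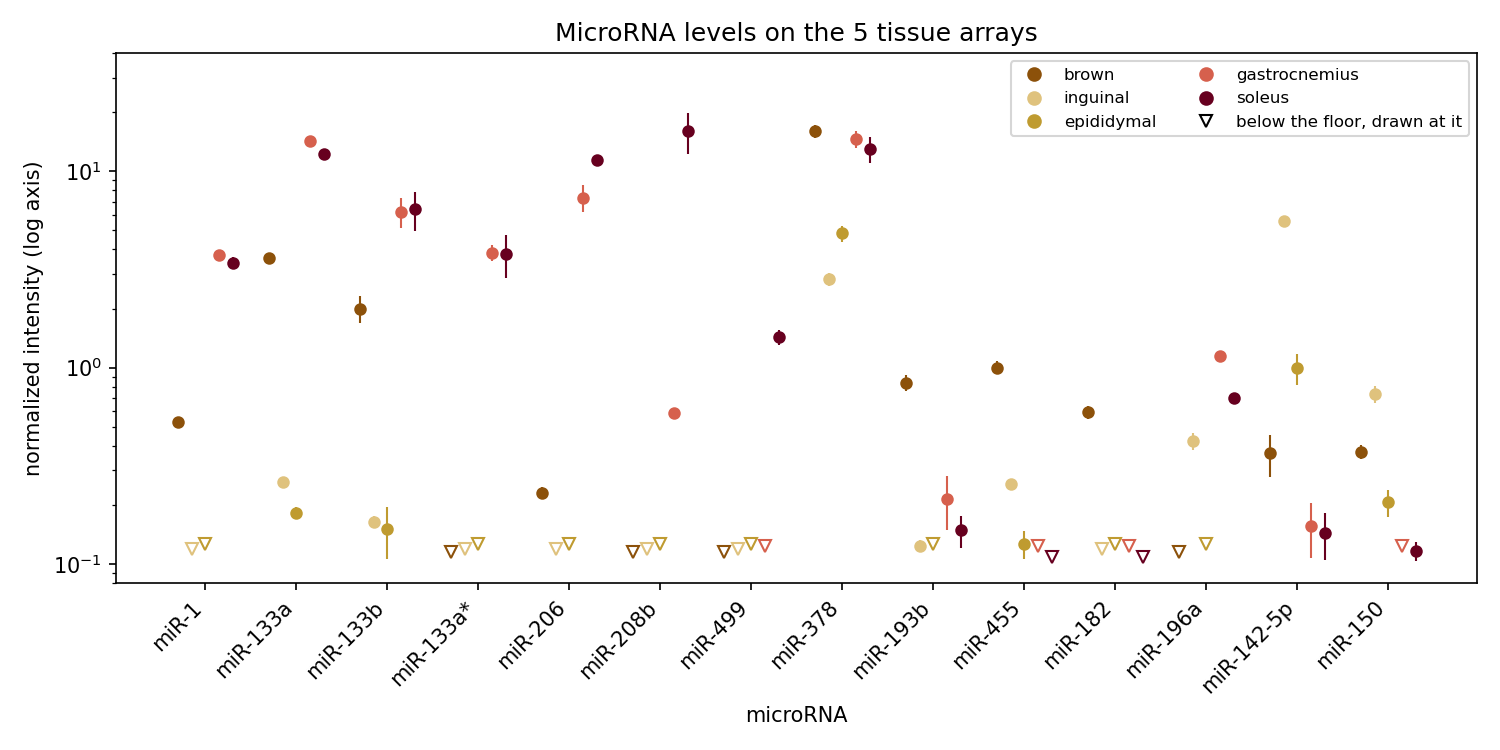
Normalized intensity (log axis) of 14 microRNAs on the 5 arrays, with filled circles and the SD of 4 spots as bars where detected, some shorter than the circle, and open triangles at the array's lowest detected value where not. miR-208b stands at 16.0 on soleus, and miR-133a at 3.60 on brown fat against 14.2 on gastrocnemius.

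Brown fat differed from both white depots by higher muscle and brown adipocyte microRNAs and by lower leukocyte microRNAs. miR-133a was 13.7-fold higher (spot SE 0.05 on the log2 scale against inguinal fat) and miR-133b 12.2-fold, both abundant in striated muscle and reported to hold back brown adipocyte formation. miR-1, another muscle microRNA, was at least 4.21-fold higher. Of the brown adipocyte list, miR-378* was at least 7.26-fold, miR-193b at least 6.63-fold, miR-182 at least 4.69-fold, miR-455 3.90-fold, miR-378 3.32-fold and miR-203 2.34-fold higher. miR-805 was 6.00-fold and miR-96 at least 3.73-fold higher. Lower in brown fat were miR-146b by 2.81-fold, miR-142-5p by 2.72-fold, miR-222 by 2.48-fold, miR-223 by 2.48-fold, miR-21 by 2.40-fold and miR-146a by 2.17-fold. miR-214 was lower by 2.03-fold, and miR-199b* was just past the limit of 2-fold.

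In all, 15 microRNAs were higher and 8 lower of 190 considered. The brown adipocyte list had 6 of 11 members above the floor higher and 0 lower, with a median log2 ratio of 1.61 at the 100th percentile of random lists. The muscle list had 3 of 5 higher, with a median of 2.12 at the 99.9th percentile. The leukocyte list had 4 of 8 lower, with a median of -1.30 at the 0.0th percentile, although miR-150 was 1.97-fold lower than in inguinal fat and 1.81-fold higher than in epididymal fat, and the smooth muscle and stromal list 2 of 7 lower, with a median of -0.98. The epithelial list had 3 of 7 higher, which were miR-182, miR-96 and miR-203, but a median of -0.51 at the 14.9th percentile; miR-182 and miR-203 are also on the brown list. Its miR-200a, miR-200b, miR-141 and miR-200c were under the floor on brown and inguinal fat, and lower in brown than in epididymal fat by at least 4.31-, 4.22-, 3.64- and 1.97-fold. The white adipocyte list went both ways, with miR-222 lower and miR-107 higher and a median of -0.43. The reported repressors had 2 of 8 higher, miR-133a and miR-133b, and a median of 0.26, whose sign turned under 4 of 6 other scalings. The miR-29 and miR-30 families had 2 of 11 higher, miR-30e and miR-30e*, with a median of 0.47 that was negative with spike-in scaling. The red cell list stood at 0.62 and the neural list, with miR-129-3p higher, at 0.49, both negative with spike-in scaling, and the endothelial list at 0.79. None of the let-7, miR-17-92, Hox or Dlk1-Dio3 members above the floor was 2-fold different from both depots, and the Hox median was -0.22. Across 6 other scalings 11 of the 15 higher and 5 of the 8 lower microRNAs stayed past 2-fold; miR-30e, miR-129-3p, miR-107, miR-203, miR-214, miR-199b* and miR-146a did not. Under at least 1 of those scalings 13 of the 23 folds were over 1.5 times smaller, with lowest values of 7.48 for miR-133a, 6.05 for miR-133b, 3.72 for miR-378*, 3.31 for miR-193b, 3.27 for miR-805, 2.59 for miR-182, 2.38 for miR-1, 2.13 for miR-455 and 2.12 for miR-96. With spike-in scaling, a setting chosen after the data were seen, 11 were higher and 25 lower.

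The inguinal array carried higher leukocyte microRNAs than the epididymal one, and which cells they came from was not tested. miR-142-5p, found in blood cells, was 5.58-fold higher (spot SE 0.14 on the log2 scale), and miR-150, which is abundant in mature lymphocytes, 3.57-fold higher (SE 0.13). miR-155 was at least 4.62-fold, miR-342-3p at least 3.42-fold and miR-142-3p 2.05-fold higher. The arms of miR-142 come from the same precursor, yet their folds differed by 2.72 times. miR-223, a myeloid microRNA, stood at 1.01-fold, miR-146b at 1.42-fold and miR-146a at 1.75-fold. miR-338-3p was at least 7.48-fold, the Hox cluster microRNA miR-196a at least 3.34-fold, miR-19a 2.60-fold, miR-19b 2.40-fold and miR-455 2.03-fold higher.

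The epididymal array carried higher epithelial microRNAs than the inguinal one, and which cells they came from was not tested. miR-200a was at least 4.18-fold, miR-200b at least 4.10-fold and miR-141 at least 3.54-fold lower in inguinal fat, and these belong to a family that marks epithelium. miR-335-5p was 5.57-fold (SE 0.09), miR-34b-5p 5.0-fold and miR-135a at least 4.74-fold lower. Lower as well were miR-190 by 2.93-fold, miR-34c by at least 2.92-fold, miR-708 by 2.85-fold and the red cell microRNA miR-144 by 2.76-fold.

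Of 172 microRNAs considered, 10 were higher and 20 lower in inguinal fat. The leukocyte list had 5 of 8 members higher and a median of 1.40 at the 100th percentile, and the miR-17-92 list 2 of 10 higher and a median of 0.73 at the 99.97th percentile. The epithelial list had 3 of 5 lower, with a median of -1.82. The red cell list of 2 members had a median of -1.13 and the endothelial list, miR-126-3p and miR-126-5p, -0.66. The median over all 133 microRNAs detected on both arrays was -0.41, so lists are read against that value. The split depended on scaling: quantile normalization gave 11 higher and 8 lower. Over 6 other scalings 9 of the 10 higher microRNAs but only 8 of the 20 lower ones stayed past 2-fold, and of those named miR-455, miR-144 and miR-34c did not. Folds over 1.5 times smaller under at least 1 scaling numbered 10 of 30, with lowest values of 3.63 for miR-335-5p, 2.84 for miR-34b-5p, 2.57 for miR-135a, 2.29 for miR-200a, 2.26 for miR-200b and 2.01 for miR-141.

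**Figure D2:**
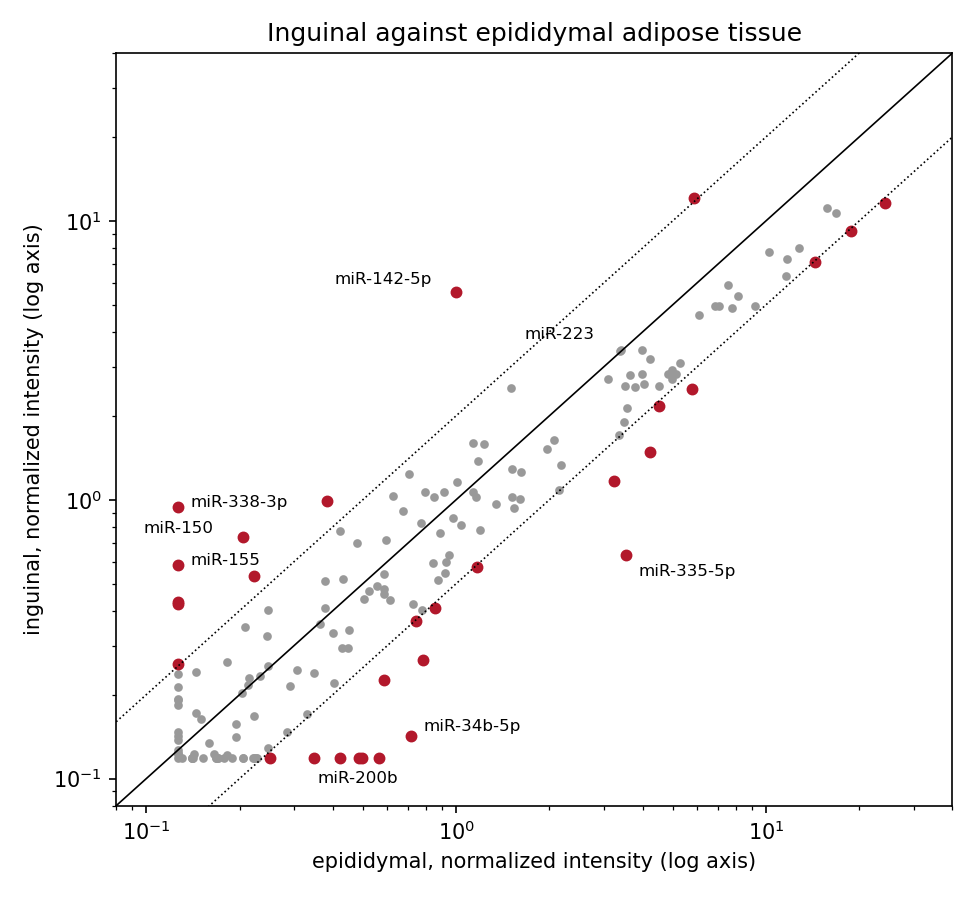
Normalized intensity of each microRNA on the inguinal array against the epididymal array (log axes), with values under the floor drawn at the array's lowest detected value. Red points are the 30 microRNAs at least 2-fold different, the solid line is equality and the dotted lines mark 2-fold.

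Soleus and gastrocnemius differed in few microRNAs, and the 2 largest were encoded in slow myosin genes. miR-208b was 27.2-fold higher in soleus (SE 0.21) and miR-499 at least 11.6-fold. miR-503 was 3.17-fold, miR-24-2* 2.42-fold and miR-706 2.01-fold higher. The other arm of the miR-503 precursor, miR-503*, went the opposite way and was 1.60-fold lower in soleus (SE 0.13). miR-193 was 5.62-fold lower in soleus (SE 0.07), miR-486 2.88-fold, miR-350 2.27-fold and the Dlk1-Dio3 microRNA miR-136 2.01-fold lower. That makes 5 higher and 4 lower of 176.

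The slow-fibre list, miR-208b and miR-499, had a median log2 ratio of 4.15. The muscle list as a whole went both ways, with 2 of 8 higher, 1 lower and a median of 0.01, whose sign turned under 3 of 6 other scalings; miR-133a stood at 5785 background-subtracted units on gastrocnemius and 5753 on soleus, and miR-206 at 2990 and 5338. The leukocyte list had a median of -0.12, positive with no scaling, the endothelial list of 0.04, negative with both 75th percentile scalings, and the red cell list of 0.07, negative with that over all probes. miR-706, miR-136 and miR-350 did not stay past 2-fold over 6 other scalings. Under these the fold of miR-208b went down to 25.3 and that of miR-499 to 6.10. Scaling by 1 factor shifted this comparison by -0.11 log2 at the lowest, so the 6.10 came with normexp and quantile normalization.

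**Figure D3:**
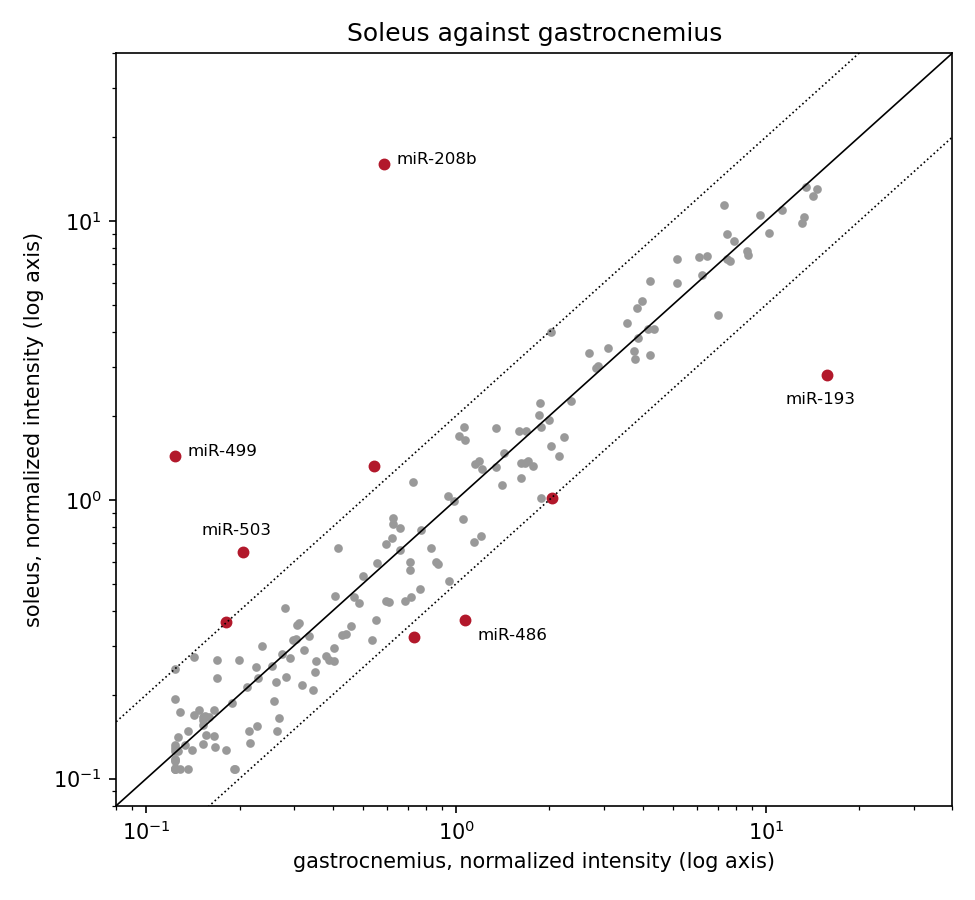
Normalized intensity of each microRNA on the soleus array against the gastrocnemius array (log axes), with values under the floor drawn at the array's lowest detected value. The 9 red points are at least 2-fold different, with miR-208b at 27.2-fold and miR-193 at 5.62-fold in opposite directions.

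In all 6 pairs of a muscle and a fat array, 7 of 8 muscle microRNAs were at least 2-fold higher in muscle. So were 7 of the 21 microRNAs of the imprinted Dlk1-Dio3 locus above the floor, of which some depended on scaling. miR-206 was 31.7-fold and miR-133a* at least 30.1-fold higher in muscle, miR-1 6.43-fold, miR-208b at least 4.65-fold, miR-133a 3.42-fold and miR-133b 3.11-fold. Of the Dlk1-Dio3 list, miR-434-3p was 7.23-fold, miR-299* at least 4.72-fold and miR-434-5p 3.55-fold higher. miR-128, on the neural list, was at least 5.73-fold higher. Lower in muscle were miR-708 by 8.89-fold, miR-203 by at least 3.43-fold, miR-148a by 3.21-fold and miR-32 by 2.93-fold. miR-142-5p, miR-652, miR-93, miR-423-5p and miR-103 were lower by 2.35-, 2.30-, 2.25-, 2.13- and 2.04-fold, and these did not stay past 2-fold over 6 other scalings, with lowest folds of 1.65, 1.64, 1.77, 1.66 and 1.59.

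There were 17 higher and 9 lower of 207. The muscle list had 7 of 8 higher and a median of 4.37, at the 100th percentile. The smallest folds of miR-133a and miR-133b were those against brown fat, where the star strand of miR-133a, from the same precursor, stood under the floor at 23 units. The Dlk1-Dio3 list had 7 of 21 higher and a median of 0.71 at the 99.96th percentile. Of those 7, miR-434-3p, miR-299* and miR-434-5p stayed past 2-fold over the scalings. miR-127, miR-411, miR-136 and miR-329 did not with spike-ins, and miR-127 and miR-411 also did not with normexp and quantile normalization. The miR-17-92 list had a median of -1.01 with 1 of 10 lower, the leukocyte list -1.27 with 1 of 8 lower, and the epithelial list -0.71 with 1 of 7 lower. The let-7 list stood at -0.21, the white adipocyte list at -0.08, positive with a 75th percentile scaling over detected probes, and the endothelial list at -0.04, positive with that scaling and with no scaling. Of 17 higher, 12 hold a bound in some pair, and with no bounds 12 microRNAs were different. Over 6 other scalings 11 of the 17 higher and 4 of the 9 lower microRNAs stayed past 2-fold. Under at least 1 of them 8 of the 26 folds were over 1.5 times smaller, with lowest values of 13.6 for miR-133a*, 4.26 for miR-434-3p, 2.94 for miR-128, 2.68 for miR-299*, 2.41 for miR-208b and 2.16 for miR-434-5p.

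Brown fat against both muscles gave 19 higher and 25 lower of 190. Higher in brown fat were miR-203 by at least 13.7-fold, miR-708 by 11.4-fold (SE 0.14), miR-455 by at least 8.09-fold, miR-32 by 5.17-fold, miR-182 by at least 4.78-fold and miR-193b by 3.90-fold. miR-96 was at least 3.80-fold, miR-107 3.37-fold, miR-148a 3.30-fold and miR-150 at least 3.02-fold higher. Lower were miR-133a* by at least 32.9-fold, miR-206 by 31.7-fold, miR-434-3p by at least 10.3-fold, miR-1 by 6.43-fold and miR-128 by at least 6.26-fold. miR-196a was at least 6.09-fold, miR-299* at least 5.16-fold, miR-208b at least 5.08-fold, miR-434-5p at least 3.88-fold and miR-411 at least 3.70-fold lower.

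The brown adipocyte list had 5 of 11 higher and a median of 1.37 at the 99.99th percentile, and miR-378, at 7126.5 units on brown fat and 5958 on gastrocnemius, was not among them. The muscle list had 7 of 8 lower and a median of -2.54, and the Dlk1-Dio3 list 8 of 20 lower and a median of -0.82. The smooth muscle and stromal list had 4 of 7 lower, with a median of -1.19, beside 3 of 3 epithelial members higher, which were miR-203, miR-182 and miR-96. The neural list went both ways, with miR-129-3p higher and miR-128 lower. The miR-17-92 list had 2 of 9 higher, miR-19b and miR-93, and a median of 1.01 at the 99.1th percentile. The red cell list had 1 of 2 higher, miR-144, and a median of 0.84. The leukocyte list had 2 of 7 higher, miR-142-5p and miR-150, and a median of 0.29 that was negative with a 75th percentile scaling over detected probes. Over 6 other scalings 10 of the 19 higher and 21 of the 25 lower microRNAs stayed past 2-fold. Those that did not were miR-103, miR-129-3p, miR-142-5p, miR-10a, miR-652, miR-423-5p, miR-19b, miR-150 and miR-93 among the higher, and miR-677, miR-199a-5p, miR-199a-3p/miR-199b and miR-335-5p among the lower. Folds over 1.5 times smaller numbered 15 of 44, with lowest values of 16.0 for miR-133a*, 7.10 for miR-203, 6.56 for miR-708, 5.34 for miR-434-3p, 4.50 for miR-455, 3.53 for miR-196a, 3.46 for miR-128, 3.16 for miR-299*, 2.93 for miR-182, 2.84 for miR-208b, 2.58 for miR-434-5p, 2.43 for miR-411, 2.40 for miR-96, 2.18 for miR-148a and 1.92 for miR-150. The liver microRNA miR-122 was under the floor on every array, at 2.0 to 12.5 units.

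Over all 10 pairs of tissues, 500 differences of at least 2-fold were counted, from 9 between the muscles to 71 between soleus and inguinal fat. The authors' deposited lists held 639 entries, of which 632 were mouse microRNAs. Their fold and floor rule applied to the deposited values gave all 632, with a largest relative gap of 0.0; the count of 500 is smaller because values under the floor were raised to it.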

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

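No test in this part was planned, and the values were looked for in probes that no comparison used in the main setting. Probes for viral microRNAs were above the floor although no infection is named: 2 on brown fat, 1 on inguinal fat, 1 on epididymal fat, 2 on gastrocnemius and 3 on soleus. mghv-miR-M1-4 reached 87.5 background-subtracted units on soleus, with a lowest array value of 22, mghv-miR-M1-7-3p 76.5 on soleus, with a lowest of 20.5, and mghv-miR-M1-8 245.5 on inguinal fat, with a lowest of 130, so it was above the floor on every array. Negative controls reached 1.5 on soleus and 1.0 on inguinal fat.

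Of the 1258 probes that the deposited table leaves unnamed, 172 were at or above the floor on brown fat, 137 on inguinal fat, 154 on epididymal fat, 162 on gastrocnemius and 164 on soleus.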

How the results depend on the processing

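Spike-in scaling, the runs without single arrays, the count with values under the floor as deposited, and the checks of calls and list signs over scalings were chosen after the data were seen; the other settings were not. No paired analysis was possible because each tissue had 1 array. Named microRNAs gave 86 values, 1 per microRNA and comparison, so some microRNAs are counted more than once. Those that moved by more than the spot spread numbered 58 of 86 with normexp and quantile normalization and 46 of 85 with a floor of 100. With a 75th percentile over detected and over all probes, 43 and 37 of 86 moved, and 41 with spike-ins. A floor of 30 moved 23, a floor from viral probes 18, no scaling 4 and median scaling 0. List medians moved by over 0.5 log2 for 12 of 60 with spike-ins, 9 of 56 with no bounds and 7 of 60 with a floor of 100. They did so for 5 each with quantile normalization and the viral floor, and 2 with a floor of 30. Scaling by 1 factor shifts all lists of a comparison alike, so the spike-in count reflects the brown against white shift of -0.70. The 75th percentile over detected probes moved 0 lists, with its largest shift at 0.498, so these counts do not measure the stability of single lists. The brightest probe per name and the series' value table hold the same values by construction, so they tested nothing.

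Counts that moved by over 1.5 times follow, against 23 for brown against white fat, 30 for the white depots, 9 for the muscles, 26 for muscle against fat, 44 for brown fat against muscle and 500 over all pairs. A 1.5-fold rule gave 41, 82, 37, 73 and 863 for these in order without muscle against fat, and a 4-fold rule 7, 8, 3, 13 and 164, with 8 for muscle against fat. All probes gave 41, 47 and 15 for the first 3 comparisons and 799 over all pairs. Without inguinal fat brown against white gave 41, without epididymal fat 43, and with spike-in scaling 36. Quantile normalization gave 19 for the white depots. A floor of 100 gave 16 and no bounds 12 for muscle against fat, and no bounds 26 for brown against muscle. The lowest correlation, 0.73, became 0.79 with a floor of 100 and 0.79 without the muscle list. Looser rules, more probes and fewer arrays to satisfy raise counts by construction, and stricter rules, a higher floor and no bounds lower them. The offset of normexp draws folds of dim probes toward 1 by construction. For the other scalings the cause was not tested.

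The percent of calls that were higher moved with scaling: brown against white, 65.2 in the main setting, gave 12 higher of 24 and 36.7 with a 75th percentile over detected and over all probes, 76.2 with no scaling and 30.6 with spike-ins. The white depots, 33.3, gave 73.5, 60.7, 47.8 and 63.3 in that order, and 57.9 with quantile normalization. The muscles, 55.6, gave 44.4 over all probes, 66.7 with median scaling, 80.0 with none and 72.7 with spike-ins. Muscle against fat, 65.4, gave 81.0 over detected probes and 11 higher of 22 with spike-ins, brown against muscle, 43.2, gave 26.2 over detected and 32.6 over all probes, and all pairs, 50.4, gave 32.0 with spike-ins. Shifts over 0.1 log2 of the median of all microRNAs ran from -0.70 (spike-ins) to 0.13 (no scaling) for brown against white, 0.27 to 0.50 for the white depots, -0.11 to 0.20 for the muscles, -0.43 to 0.15 for muscle against fat and -0.33 to -0.25 for brown against muscle. Of lists with 3 or more members, the 18 medians outside the central 95% kept their sign under all 6 scalings; 25 of the 60 turned under at least 1, the largest of these at 0.47 in size. Signal over background limits this: a microRNA under the floor on 1 array gives only a bound.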

Other observations

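The arm-pair test was written before its value was seen; the tests of muscle shares, of a shared response curve, of arms parting, of miR-223, of the leukocyte percentile, of the spike-in quotient and of small RNA controls were chosen after. The bounds as first set would have excluded arm compression, leukocytes of every kind and a weaker scan; the conditions on the resampled interval, the miR-142 arms and the highest spike-in ratio were added after those values were seen, and each left its explanation open. A test of the inguinal scaling by spike-ins, written beforehand, was replaced by the percentile because its factor raised every fold between these arrays and so had no bearing, and a test of the miR-133a strands, which had met its bound, by arms parting because it restated the pattern.

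Levels of miR-196a and miR-196b, from Hox clusters, split the tissues in a way that fat and muscle do not. miR-196a stood at 177.5 background-subtracted units on inguinal fat, 465.5 on gastrocnemius and 329 on soleus, and at 0.5 on brown fat and 3.5 on epididymal fat; miR-196b ran alongside at 51.5, 105.5, 89.0, 1.0 and 6.5. miR-10a and miR-10b were detected everywhere, at 688 to 2084 and 784.5 to 1409.5 units, and the Hox list lay inside the central 95% of random lists in all 5 comparisons. miR-193, the brightest mouse probe on brown and epididymal fat and gastrocnemius, stood at 10094.5, 9617 and 6438.5 units there, 4856.5 on inguinal fat and 1315 on soleus. The epididymal array alone held miR-200a, miR-200b, miR-200c and miR-141 above the floor, at 197, 193, 90.0 and 166.5 units, along with miR-34c at 137.5.

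Muscle microRNAs were present on the brown fat array, which may reflect expression in brown fat, untested here, or muscle taken with the fat. Muscle tissue with the gastrocnemius profile, seen by linear probes, would leave every muscle microRNA at the same share of its gastrocnemius level. The highest share of a detected one was 10.2 times the lowest, miR-133b at 32.2% and miR-206 at 3.15%. Shares of the soleus level ran from 2.03% for miR-206 to 33.8% for miR-486. Muscle beside brown fat was on no array, and its proportions of these microRNAs are unknown. A response curve shared by all probes that flattens with brightness is argued against: it gives brighter probes the higher shares, yet miR-133a* and miR-206, at 1570 and 2989.5 units on gastrocnemius, stood at no more than 3.00% and at 3.15%, and the dimmer miR-1, at 1529 units, at 14.2%, or at least 4.72 times the share of miR-133a*. A response of each probe's own stays open, and the arm values do not decide it. Arms parting was read as the smaller arm log2 ratio over the larger, no more than 0.391 for miR-133a and its star strand. This quotient was as low in 6 of 12 other precursors with an arm ratio of 2-fold or more and both arms going the same way. Small ratios pass it easily, and those arm ratios were no more than 2.54 log2 against at least 5.06 for the star strand. In fold size, the arms of 1 precursor differed by no more than 5.25 times where both were above the floor on both arrays. Arms under the floor, as the star strand of miR-133a was on brown fat, are left out there. That limits how far arms can part. miR-133a at 25.4% of gastrocnemius and its star strand at no more than 3.00% lay further apart. Over 117 precursor and array pairs the brighter arm had the smaller ratio in 54.7%, with a resampled 95% interval of 40.4 to 69.2. That interval spans the 55% and the 60% set beforehand. Muscle tissue like gastrocnemius as the whole cause is argued against for linear probes or a shared curve. Muscle tissue cannot be told apart from other sources while each probe's own response and the profile of muscle beside brown fat are unknown.

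Leukocyte microRNAs were higher on the inguinal array than on the epididymal one, which may be a difference between the tissues, untested here. Whether it lay in the fat itself or in other tissue taken with the fat was not tested either. Scaling of the inguinal array is argued against: it moves the list and random lists of like level alike, yet the list's median stood at the 100th percentile of these, under the deposited and 6 other scalings. Scaling by 1 factor leaves a percentile nearly where it was, so quantile normalization bears on it most, and with it miR-150 was 3.02-fold higher. More leukocytes of every kind would raise each member, yet miR-223 stood at 1.01-fold and miR-146b at 1.42-fold, with miR-146a at 1.75-fold. Those folds depend on scaling, and with spike-ins they were 1.29-, 1.81- and 2.24-fold. In the main setting the median over all microRNAs detected on both arrays was itself -0.41 log2. The arms of miR-142 also differed by 2.72 times, so probes need not follow their cells alike. More leukocytes of every kind therefore cannot be told apart from a difference in 1 cell type.

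Spike-in controls were dimmer on the inguinal array, at 0.515 of brown fat (0.455 to 0.557 over 5 controls), as were Hy3 landmarks at 0.567, while the median microRNA stood at 0.788. On the epididymal array spike-ins stood at 0.620 (0.400 to 0.744) with landmarks at 0.931 and microRNAs at 0.982, so dim spike-ins were not particular to the inguinal array and occurred without dim landmarks. A weaker scan of the whole array could account for the first values, but the microRNA ratio was 1.53 times the spike-in ratio, or 1.41 times that of the control with the highest ratio, and tissues may differ in microRNA content. A larger share of microRNA in the labelled RNA may add to it, but small RNA controls stood at a median of 1.20 of brown fat and ranged from 0.574 to 2.19, so with 1 array per tissue these explanations cannot be told apart.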
